A study of Mus musculus with 80 samples.

How the data were processed

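The values are the deposited gene counts: per the labels and the numbers themselves, the unit is the count of reads per gene and library, all whole, over 31017 gene symbols, of which 1126 have no count in any library. Per the submitters' processing notes the upstream work used Scanpy and DESeq2 1.26.0 with the mouse genome builds GRCm38 and mm10; the aligner and the counting tool are not stated. Gene coordinates come from the GENCODE vM21 annotation of GRCm38, which holds 30416 of the symbols. Age and mouse code come from the deposited sample table; the sex of a line was read from 4 Y-linked genes, since that table gives none. Line pairing across stages follows those codes.

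Differential tests used edgeR 4.0.16 (TMM scaling, its default filter on low counts, quasi-likelihood F test) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Comparisons between stages had the line as a block. The AT2, alveolar organoid and P1 comparisons were fitted together with the tumor organoid libraries of the same 2 lines to estimate the spread. Age was tested on counts summed over passages 2 to 8 per line, at P2, at P8 and at P0, and as an interaction with the P2 to P8 change. Log2 fold changes are fitted values with the default prior count of edgeR, so those of genes near 0 counts can be very large. A prior count of 1 was used for log2 CPM of single libraries or lines, not in the fits. SE is the absolute log2 fold change over the square root of the F statistic, an approximate standard error. The alternative tool was DESeq2 1.42.0 (Wald test), and limma 3.58.1 gave the camera list test. Camera used a preset correlation of 0.01 between genes and was run again with the correlation estimated from the data; its p-values are adjusted over the lists tested in a comparison, 32 or, from P0 to P2 and for age at P0 and at P8, 31, where 1 list had too few measured genes. Lists covered lung cell identity, other cell types, stress responses, metabolism, iron, antigen presentation, cell cycle and sample quality. The lists, groups, comparisons, alternatives to try and rule for named genes were written before the data were examined.

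Named genes come from 3 parts of that rule. The first part takes, among genes past the threshold with a mean log2 CPM of 2 or more and the same direction in every line (for age, at most 1 line out of order), the 10 with the greatest change each way. The second takes the members of each list with the smallest adjusted p, up to 4 where the list passed and up to 2 where it did not. The third is a fixed set: Nupr1, Lcn2, Tfrc, Fth1, Ftl1, Slc40a1, Trp53, Kras, Sftpc, Nkx2-1, Cdkn2a, Hmga2 and Mki67. Folds against a group with no counts use a floor of 3 counts over the group.

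Planted changes gave the power of the designs named next. None were planted for age at P8 or at P0, the interaction, or alveolar organoid against P1. Of genes shifted by log2 2, edgeR recovered 57% for age with passages summed, 97% between P2 and P8, 82% between P0 and P2 and 38% between AT2 and alveolar organoid; at log2 1 it recovered 14%, 71%, 19% and 2%. Of its calls in the same order 2.74%, 2.33%, 6.48% and 4.76% were false, and of those by DESeq2 30.7%, 18.9%, 22.9% and 23.4%. No sequencing batch or date is given for any library.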

Results

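The deposited counts cover 80 sequencing libraries from 10 mouse lung organoid lines, each line grown from the cells of 1 mouse. Per the labels, alveolar type 2 (AT2) cells, which make lung surfactant, were isolated from mice with conditional Kras and Trp53 alleles and made into tumor cells outside the animal. The deposited sample table calls 5 lines young (AF1165, AF1181, AF1183, AF1337, AF1338) and 5 aged (GH1394, GH1397, GH1493, GH2108, KW1401). Tumor organoids of passages 2 to 8 (P2 to P8) have 10 libraries each, 1 per line. P0 organoids have 4 libraries. They are labelled normal, but their columns in the count file add the word Cre, so whether P0 precedes the Cre treatment is not known. P1 tumor organoids, alveolar organoids and AT2 samples have 2 each, from AF1338 and GH1493. The lowest total of counts in genes was 4.15 M (M, 1e+06 counts). Medians were 5.62 M at P2, 5.81 M at P6, 10 M at P7 and 9.67 M at P8. The line is the replicate throughout. Levels are counts per 1e+06 counts in genes (CPM), given as mean ± SD over lines, scaled within each comparison.

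Tumor organoids at P2 held far less of the AT2 program than the P0 organoids of the same 4 lines. Sftpc, which encodes surfactant protein C (chromosome 14, 70520949 to 70524081), fell from 82200 ± 16100 to 6330 ± 3080 CPM (log2 fold change -3.75, SE 0.375, adjusted p = 0.000832). Lyz2, which encodes lysozyme M, fell from 10200 ± 223 to 49.7 ± 34.6 CPM (-7.88, SE 0.486). Napsa, a protease that processes surfactant protein B, fell from 4470 ± 361 to 84.6 ± 63 CPM (-5.94, SE 0.425). Some genes of stomach and gut epithelium rose in all 4 lines. Ctse, which encodes cathepsin E, rose from 10.2 ± 4.49 to 702 ± 266 CPM (log2 fold change 6.16, SE 0.269). Hnf4a, a transcription factor of liver and gut, rose from 5.9 to 77.6 CPM (3.74, SE 0.403). Hmga2, a chromatin protein of embryonic and tumor cells, rose from 7.65 ± 1.96 to 34.8 ± 2.64 CPM (2.25, SE 0.203).

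Of 24 measured AT2 identity genes, 22 fell and 0 rose between P0 and P2 (22 adjusted over the list alone; list test adjusted p = 4.23e-21, and adjusted p = 0.28 with an estimated correlation). Antigen presentation genes fell too. All 7 class II genes fell (7 adjusted over the list alone), such as H2-Aa at log2 fold change -6.13 (SE 0.285). The list has adjusted p = 5.32e-14, and adjusted p = 0.234 with an estimated correlation. Of 13 class I genes 10 fell and 0 rose (10 adjusted over the list alone), such as Psmb8, a subunit of the immunoproteasome (-5.65, SE 0.371), and Tap1, a peptide transporter (-5.31, SE 0.378). That list has adjusted p = 9.66e-08, and adjusted p = 0.28 with an estimated correlation. Among 24 cholesterol synthesis genes 19 fell and 0 rose (19 adjusted over the list alone). Lss, which closes the sterol ring, was at -2.27 (SE 0.194) and Pmvk, a mevalonate pathway kinase, at -2.14 (SE 0.133). Among 27 fatty acid genes 19 fell and 4 rose (19 and 4 adjusted over the list alone). Scd1, which makes monounsaturated fatty acids, went from 27700 ± 4550 to 983 ± 458 CPM. The cholesterol list has adjusted p = 1.87e-08 (adjusted p = 0.398 with an estimated correlation) and the fatty acid list 9.66e-08 (adjusted p = 0.326 with an estimated correlation).

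Markers of fibroblasts, another cell type, were present at P0 and fell at P2. Of 16 measured, 14 fell and 1 rose (14 and 1 adjusted over the list alone; list adjusted p = 3.46e-11, and adjusted p = 0.326 with an estimated correlation). Col3a1, a fibrillar collagen, went from 141 ± 50.9 to 1.9 CPM (log2 fold change -6.34, SE 0.567). Mgp, a matrix protein, went from 421 ± 135 to 0.171 CPM (-11.09, SE 0.447). The matrix proteoglycan Bgn went from 474 to 2.17 CPM (-7.82, SE 0.481). Grem1, a BMP antagonist, had 3 counts over the 4 P2 libraries and was 1840-fold lower (counting interval 631 to 8940). Genes of the cell cycle rose, 35 of 40 with 0 lower (35 adjusted over the list alone; list adjusted p = 1.96e-11, and adjusted p = 0.481 with an estimated correlation). They include the helicase subunit Mcm4 (2.02) and Uhrf1, which maintains DNA methylation (2.07). Transitional, Krt8-high alveolar state genes rose, 16 of 24 with 0 lower (19 adjusted over the list alone; list adjusted p = 2.08e-10, and adjusted p = 0.28 with an estimated correlation). The keratins Krt7 and Krt18 were at 2.79 (SE 0.207) and 2.13 (SE 0.205), the transporter Slc4a11 at 4.18 (SE 0.325) and the integrin subunit Itgb6 at 1.78 (SE 0.144). Of 13 gut-like genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 1.04e-07, and adjusted p = 0.179 with an estimated correlation). The annexin Anxa10, of stomach epithelium, rose from 14.6 to 168 CPM (3.48, SE 0.278). Cdx2, an intestinal transcription factor, had no counts at P0 and was at least 95.4-fold higher at P2, against a floor of 3 counts over the group. Such floors and intervals cover counting error only.

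Iron genes went both ways, 6 up and 10 down of 30 measured (6 and 10 adjusted over the list alone; list adjusted p = 0.102). The iron exporter Slc40a1 rose from 7.55 to 22.9 CPM (log2 fold change 1.63, SE 0.251). The ferritin heavy chain Fth1 (-1.04, SE 0.163), the transferrin receptor Tfrc (-0.81, SE 0.15) and the iron-binding protein Lcn2 (1200 ± 254 to 19.1 ± 18.9 CPM; -6.51, SE 0.802) fell. Trp53, the tumor suppressor that the mouse alleles allow to be deleted, fell from 21.3 ± 4.37 to 11.4 ± 1.86 CPM (-0.85, SE 0.229, adjusted p = 0.0251). The cyclin-dependent kinase inhibitor Cdkn2a rose from 2.22 to 26.9 CPM (3.52, SE 0.387). Over all genes 4894 of 12131 tested passed an adjusted p under 0.05, 2488 up and 2406 down. Of these, 4546 had a mean log2 CPM of 2 or more and changed the same way in all 4 lines. The libraries also differ in the share of reads outside genes, with medians of 4.84% at P0 and 15.3% over P2 to P6 of the 8 lines without AT2 libraries. With that share as a covariate 2234 genes passed. In AF1337, whose P2 library has a share of 3.45%, 93.3% of the 4321 genes called in the other lines had the same direction.

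Alveolar organoids, the cultured stage between the AT2 samples and P1, carried high levels of mesenchymal genes in both AF1338 and GH1493. In the GH1493 alveolar organoids, of a male line, Xist, an RNA of the inactive X chromosome, was at 72.8 CPM. It was at 8.88 CPM in AF1165 P0 and at 0 to 1.33 CPM in the 37 other libraries of male lines. Whether all RNA of the GH1493 organoid sample came from that line was not tested. From AT2 to alveolar organoid Col3a1 rose from 79 to 4380 CPM (log2 fold change 5.8, SE 0.308, adjusted p = 0.000245). Col1a1, the main collagen of connective tissue, went from 24.7 to 2220 CPM (6.52, SE 0.85). From alveolar organoid to P1 Col3a1 fell to 13.6 CPM (-8.35, SE 0.347). Acta2, smooth muscle actin, fell from 1810 to 1.73 CPM (-10.03). Ccng1, a gene induced by p53, rose from 69.7 to 567 CPM (3.02, SE 0.207) and then fell to 90.6 CPM (-2.67, SE 0.204). Trp53 itself fell from 74.7 ± 6.19 CPM in alveolar organoids to 11.6 ± 6.94 CPM at P1 (-2.79, SE 0.681, adjusted p = 0.0203).

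Of 22 fibroblast markers 13 rose and 2 fell from AT2 to alveolar organoid (14 and 3 adjusted over the list alone; list adjusted p = 4.34e-09, and adjusted p = 0.25 with an estimated correlation). From alveolar organoid to P1 1 rose and 14 fell (1 and 18 adjusted over the list alone; list adjusted p = 1.06e-19). That fall is the call that holds with the estimated correlation (adjusted p = 0.0482 with an estimated correlation). The other lists called in any comparison do not pass with it. Of 27 p53 targets 8 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p = 0.000202, and adjusted p = 0.25 with an estimated correlation). At P1 1 rose and 7 fell (1 and 13 adjusted over the list alone; 2.46e-05, and adjusted p = 0.127 with an estimated correlation). Phlda3 and Mdm2, both induced by p53, are among them. Their log2 fold changes were 4.27 and 1.21, then -3.83 and -1.03. Epithelial junction genes took the opposite course. The 2 alveolar organoid libraries enter both steps, so a change that turns back at P1 is partly built in. This holds for junction genes, p53 targets and fibroblast markers alike. Across genes, the AF1338 AT2 sample also had a correlation of 0.956 with AF1338 P1 and 0.735 with the GH1493 AT2 sample. In alveolar organoids 12 of 24 were lower and 0 higher (15 lower and 1 higher adjusted over the list alone; 1.4e-06, and adjusted p = 0.286 with an estimated correlation). At P1 15 were higher and 0 lower (19 higher adjusted over the list alone; 2.15e-11, and adjusted p = 0.127 with an estimated correlation). The tight junction gene Cldn7 went from 368 to 121 and then to 409 CPM. Glycolysis genes rose at P1, 12 of 17 with 0 lower (14 adjusted over the list alone; 4.88e-08, and adjusted p = 0.461 with an estimated correlation). Lactate dehydrogenase Ldha went from 1470 to 5800 CPM (1.96). Slc40a1 rose from 1.27 to 33.1 CPM and then fell to 5.51 CPM (4.41, SE 0.845, and -2.69).

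Sftpc was at 50100 CPM in the AF1338 and 207000 CPM in the GH1493 AT2 sample. It was at 61200 and 55900 CPM in their alveolar organoids, so it was higher in one line and lower in the other, and at 40600 and 49000 CPM at P1. Neither step passed (adjusted p = 0.844 and 0.767; n = 2 lines). Of 13619 genes 1868 passed from AT2 to alveolar organoid (1055 up, 813 down) and 2050 from alveolar organoid to P1 (1002 up, 1048 down). The spread was drawn from all stages of these 2 lines. The second count was 4172 without the AF1338 AT2 sample and 5491 with only the 4 libraries compared. With the 4 AT2 and alveolar organoid libraries alone 0 passed in edgeR, with 1250 at an unadjusted p under 0.05. The AT2 samples of the lines differ: Hnf4a was at 24.5 CPM in AF1338 and 0 in GH1493, and Krt8, a keratin of simple epithelium, at 5210 and 846 CPM. Leaving out AF1338 or GH1493 took away the AT2, alveolar organoid and P1 libraries of that line. This left 1 library per stage, with the spread drawn from the other libraries of all lines, so no count is given. Of 22 genes of RNA quality and tissue dissociation 10 fell and 0 rose from AT2 to alveolar organoid (15 lower and 1 higher adjusted over the list alone).

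Between P2 and P8 many AT2 genes fell further. Sftpc fell from 8650 ± 8340 to 857 ± 2370 CPM (log2 fold change -8.08, SE 1.67, adjusted p = 0.00661; lower in 9 of 10 lines). KW1401 was at 7570 CPM at P8, and the mean of the 9 other lines was 111 ± 188 CPM. Lyz2 fell from 89.6 ± 105 to 0.471 ± 1.23 CPM (-8.03, SE 0.747; lower in 10 of 10), and Lamp3, a lamellar body protein, from 84.5 ± 72.3 to 6.77 ± 18.5 CPM (-6.26, SE 1.13). Without KW1401 the P8 means were 0.0912 ± 0.274 and 0.98 ± 2.33 CPM, and that of the phosphate transporter Slc34a2 was 6.1 ± 8.16 CPM. All 4 genes also passed without line KW1401 (Sftpc at log2 -8.68, adjusted p = 0.00414). Rising genes included En1 and Foxg1, transcription factors of the embryonic brain. These went from 1.44 ± 2.72 to 15.4 ± 10.1 CPM (4.01, SE 0.462) and from 3.67 ± 4.28 to 29.4 ± 18.1 CPM (3.32, SE 0.369), each higher in 10 of 10 lines. Tnfaip2, a gene induced by TNF, rose from 22.8 ± 19.9 to 179 ± 121 CPM (3.06, SE 0.289). Hmga2 rose from 30.1 ± 9.11 to 55.8 ± 27.5 CPM (0.74, SE 0.16), but between P2 and P6 its log2 fold change was -0.299 (adjusted p = 0.24). The course of Sftpc and Hmga2 in every line is drawn in the figure of passage markers.

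**Figure D1:**
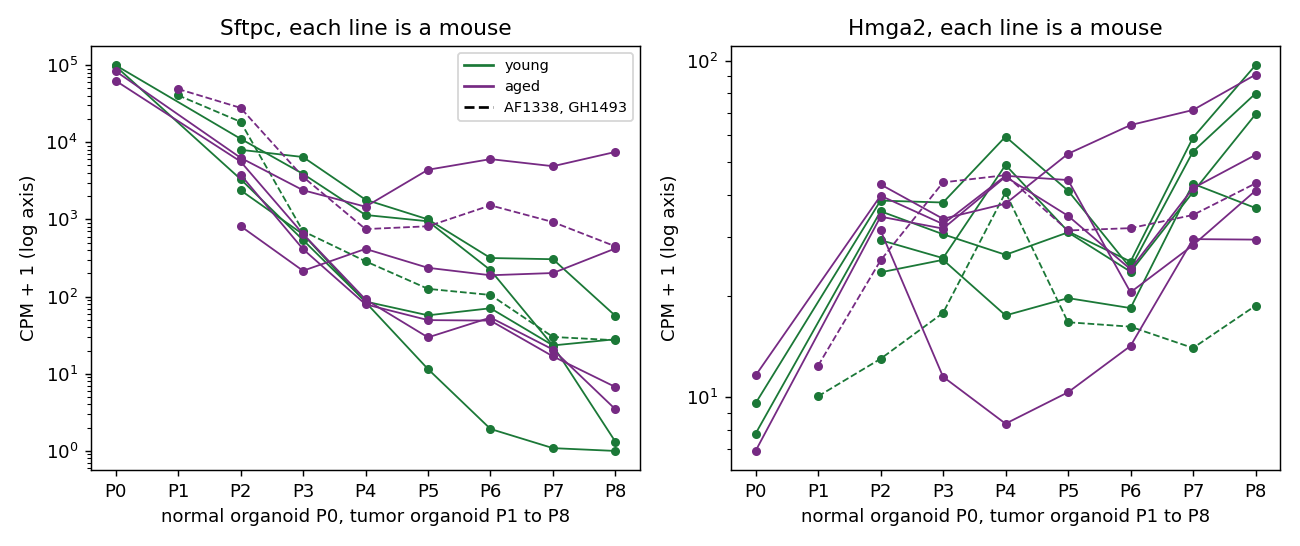
Sftpc and Hmga2 in CPM in each line from the earliest stage to P8; green, young lines; purple, aged lines; dashed, AF1338 and GH1493.

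Of 23 AT2 identity genes 14 fell and 0 rose between P2 and P8 (16 adjusted over the list alone; list adjusted p = 2.3e-10, and adjusted p = 0.274 with an estimated correlation). Besides Sftpc and Lyz2 these include Slc34a2 (501 ± 515 to 34.2 ± 89.4 CPM; log2 fold change -6.35, SE 1.01) and Lpcat1, which remodels surfactant lipids (-2.12, SE 0.356). The lung claudin Cldn18 fell from 806 ± 377 to 202 ± 151 CPM (-2.46, SE 0.38). The class II gene H2-Ab1 fell from 16.4 ± 23.5 to 0.118 ± 0.245 CPM (-6.65, SE 0.594). It is 1 of 2 called among 4 class II genes (2 adjusted over the list alone; list adjusted p = 0.00207, and adjusted p = 0.283 with an estimated correlation). Aco1, the iron-sensing RNA-binding aconitase, fell in 10 of 10 lines from 286 ± 72.2 to 133 ± 31.9 CPM (-1.15, SE 0.109). Of 29 iron genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; list adjusted p = 0.338). The risen ones include Slc40a1 (0.8, SE 0.161) and Fth1 (0.65, SE 0.161), which was at -0.039 in AF1338 and GH1493 alone. Lcn2 went from 20.8 to 169 CPM without passing (2.94, SE 1.13, adjusted p = 0.0775). In AF1338 and GH1493 alone it fell (-6.478, adjusted p = 0.0158).

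Many genes of stress and metabolic lists rose over the same interval in the 10 lines. Of 19 hypoxia response genes 16 rose and 0 fell (17 and 1 adjusted over the list alone; list adjusted p = 7.93e-12, and adjusted p = 0.274 with an estimated correlation). They include Egln1, an oxygen-sensing hydroxylase (log2 fold change 2.67, SE 0.448), Ero1l, an endoplasmic reticulum oxidase (2.99, SE 0.534), and the angiogenic factor Vegfa (1.29, SE 0.17). Of 31 integrated stress response genes 21 rose and 0 fell (26 and 2 adjusted over the list alone; 8.78e-12, and adjusted p = 0.274 with an estimated correlation). The cystine transporter Slc7a11 and the serine synthesis gene Psph are among them, at 1.22 (SE 0.164) and 0.77 (SE 0.115). Cholesterol synthesis genes had 17 of 24 higher and 0 lower (17 adjusted over the list alone; 8.61e-09, and adjusted p = 0.283 with an estimated correlation). Msmo1 and Fdps, enzymes of the pathway, were at 0.92 (SE 0.139) and 0.69 (SE 0.109). Glycolysis had 14 of 17 higher, the glucose transporter Slc2a1 at 0.72 (SE 0.145) among them, and 0 lower (15 adjusted over the list alone; 1.13e-07, and adjusted p = 0.296 with an estimated correlation). NF-kB targets had 11 of 25 higher and 1 lower (15 and 1 adjusted over the list alone; 7.35e-07, and adjusted p = 0.274 with an estimated correlation). The chemokine Cxcl2 was at 2.4 (SE 0.447). Senescence genes had 12 of 23 higher and 2 lower (13 and 2 adjusted over the list alone; 2.53e-05, and adjusted p = 0.274 with an estimated correlation). The cell cycle inhibitors Cdkn1a and Cdkn2a were at 1.46 (SE 0.301) and 0.83 (SE 0.205). Of 40 cell cycle genes 0 rose and 1 fell (list adjusted p = 0.0573).

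The libraries differ in ways that largely follow passage in 8 of the lines, as the figure of library sets shows. In those 8 lines the share of reads outside genes had a median of 15.3% over P2 to P6 and 3.77% at P7 and P8. In AF1338 and GH1493 it was 4.24% over all stages. In the 8 lines 3 of the 40 libraries of P2 to P6 lie under 6%: AF1337 P2 (3.45%), AF1337 P4 (2.78%) and AF1165 P5 (4.93%). Sftpc and Lyz2 fell in both sets of lines. The log2 fold change of Sftpc was -8.19 (adjusted p = 0.0117) in the 8 and -7.62 (adjusted p = 0.0226) in the 2, and that of Lyz2 -7.5 and -9.61 (adjusted p = 0.000209 and 0.013). En1, Foxg1 and Tnfaip2 had log2 fold changes of 3.92, 3.33 and 3.01 in the 8 lines and 4.11, 3.19 and 3.31 in the 2. In the 2 lines none of the 3 passed (adjusted p = 0.119, 0.0699 and 0.158). Over the libraries of 6% or more, median En1 was 0.907 CPM at P2 (n = 7 lines) and 14.2 CPM at P6 (n = 8 lines). The methyl-CpG binding protein Mbd2 had medians of 12.2 CPM at P2, 16.3 at P6 and 154 at P7 in the 8 lines, against 15.4, 15.3 and 12.4 in the 2. In AF1337 P2, AF1337 P4 and AF1165 P5 it was at 18.6, 15.2 and 16.2 CPM. Likewise the RNA-binding protein Ybx3 had a log2 fold change of 3.58 in the 8 lines and 0.59 in the 2, and Egln1 3.24 and -0.05. Cdx2 rose in the 10 lines together (2.46, SE 0.448), with 2.93 in the 8 and 0.6 in the 2. For whole lists, the log2 change of the mean over the genes was taken in each line, and its median over lines is given. The hypoxia list had 1.461 in the 8 lines and 0.491 in the 2, the integrated stress response list 0.857 and 0.435, and the cholesterol list 0.463 and 0.271. In the same order the glycolysis list had 0.798 and 0.513, the NF-kB list 1.099 and 0.205 and the senescence list 1.097 and 0.25.

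**Figure D2:**
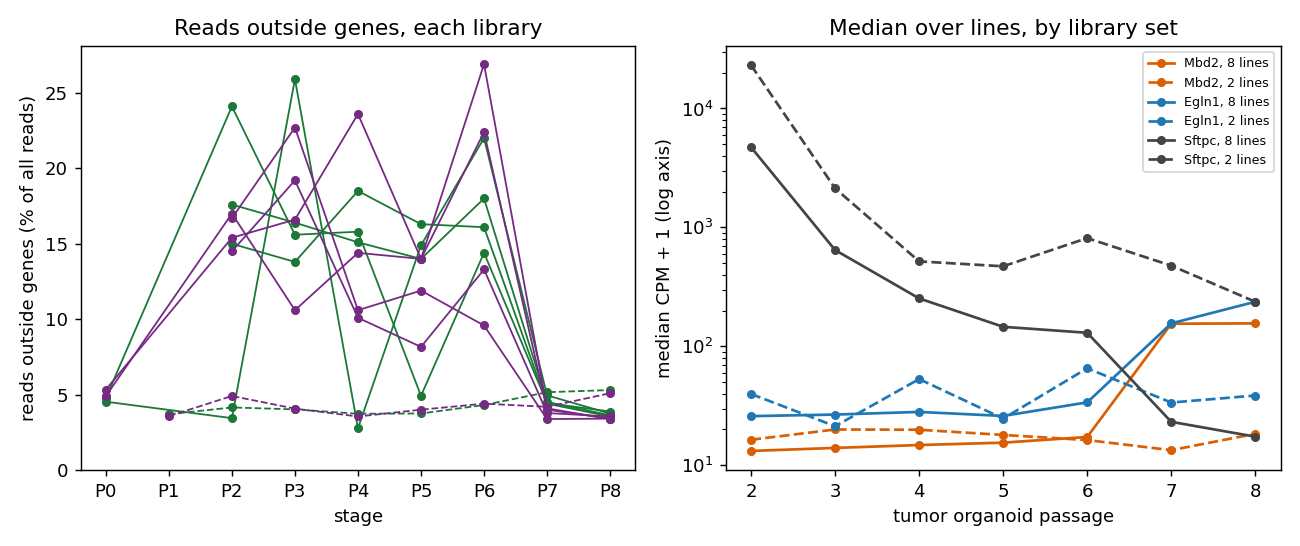
Left, percent of reads outside genes in each library by stage; right, median CPM of Mbd2, Egln1 and Sftpc by passage in the 8 lines without AT2 libraries (solid) and in AF1338 and GH1493 (dashed); Mbd2 and Egln1 were chosen after their values were seen.

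Over all genes 2712 of 11682 tested passed between P2 and P8, 1450 up and 1262 down (53.5% up). Of these, 853 changed by more than 2-fold, and 647 had a mean log2 CPM of 2 or more and changed the same way in all 10 lines. Agreement between lines was not counted for called genes of lower level. In AF1338 and GH1493 alone 170 passed (7 up, 163 down), and 87 of these are among the 2712. With the share of reads outside genes as a covariate 5 passed. At P7 and P8 of the 8 lines passage and library set cannot be told apart.

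Age separated the tumor organoids by 1 gene. Dmtn, which encodes dematin, an actin-bundling protein of the red cell skeleton (ENSMUSG00000022099.17; chromosome 14, 70601263 to 70636048, minus strand), was higher in the aged lines. It was at 58.2 ± 25.5 against 2.05 ± 1.01 CPM with passages 2 to 8 summed per line (28.2-fold; log2 fold change 4.82, SE 0.538, adjusted p = 0.0336; n = 5 lines each). At P2 it was at 56.1 ± 14 against 3.01 ± 1.59 CPM (4.22, SE 0.389, adjusted p = 0.00221). Over the 40 libraries of each age group it ran from 11.8 to 114 CPM in aged and from 0 to 4.57 CPM in young lines, as the figure of Dmtn shows. The iron genes fixed beforehand did not pass. The ferritin genes Fth1 and Ftl1 were at 2140 ± 481 and 4400 ± 796 CPM in young and 2650 ± 1170 and 5600 ± 813 CPM in aged lines (log2 0.31, SE 0.269, adjusted p = 1, and log2 0.35, SE 0.161, adjusted p = 0.974). The stress-induced regulator Nupr1 was at 517 ± 191 CPM in young and 498 ± 128 in aged lines (log2 -0.05, SE 0.236), and Lcn2 at 67.5 ± 69.9 and 56.5 ± 42.3 (-0.25, SE 0.893). Tfrc was at 220 ± 39.6 and 213 ± 85.6 (-0.05, SE 0.246) and Slc40a1 at 42.3 ± 22.6 and 31.8 ± 23.8 (-0.42, SE 0.476). These 4 genes each have adjusted p = 1.

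**Figure D3:**
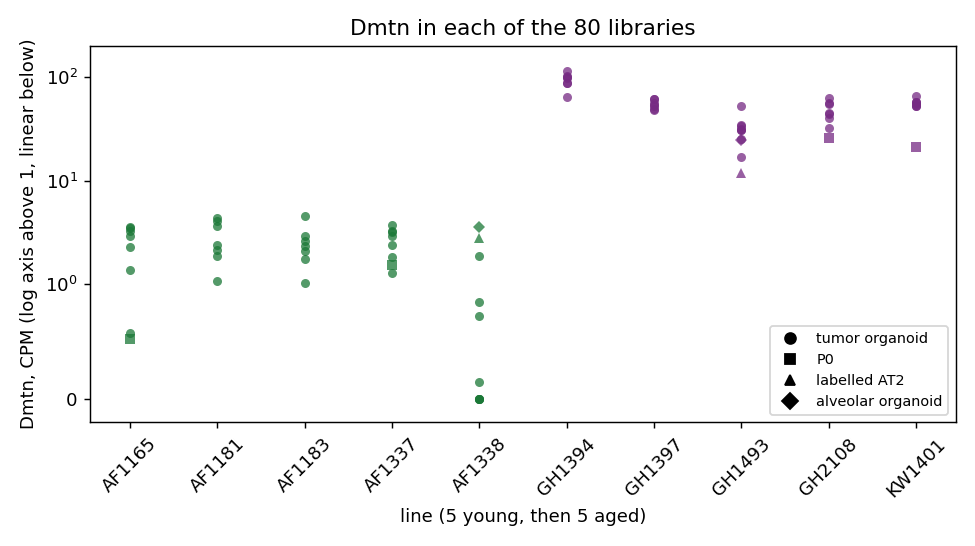
Dmtn in CPM in each of the 80 libraries by stage; green, young lines; purple, aged lines.

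The list test with the preset correlation called further differences by age, with 0 of the lists' genes past the threshold over all genes. Some of these follow. With passages summed, 24 AT2 identity genes had 0 called and a median log2 difference of 0.446, aged over young (0 adjusted over the list alone; list adjusted p = 5.94e-05, and adjusted p = 0.832 with an estimated correlation). Sftpd, surfactant protein D, was at 120 ± 44.1 CPM in young and 357 ± 165 in aged lines (1.58, adjusted p = 0.713). Sftpb, surfactant protein B, was at 420 ± 276 and 1180 ± 564 CPM (1.5, adjusted p = 0.896), and the lung transcription factor Nkx2-1 at 73.9 ± 44.6 and 154 ± 51.2 CPM (1.06, adjusted p = 0.968). At P2 the AT2 median was -0.066 over 23 genes with 0 called (0 adjusted over the list alone; list adjusted p = 0.766), and Sftpc was at 8720 ± 6560 CPM in young and 8930 ± 10800 in aged lines. At P8 the AT2 median was 1.485 over 18 genes, 7 of them higher adjusted over the list alone and 0 over all genes (list adjusted p = 4.06e-09, and adjusted p = 0.186 with an estimated correlation). Sftpc was then at 21.7 ± 22.8 CPM in young and 1670 ± 3250 in aged lines (6.27, SE 2.12, adjusted p = 0.598). Without KW1401 the aged mean was 218 ± 248 CPM, with a log2 difference of 3.32 (adjusted p = 0.908). The difference is not specific to AT2 genes. Airway club, basal and ciliated cell markers, of other cell types, had medians of 0.517 over 16 genes with passages summed and 0.766 over 8 genes at P8, with 0 called (2 higher adjusted over the list alone in each). Their list adjusted p is 0.00975 and 0.000223, with adjusted p = 0.723 and adjusted p = 0.186 with an estimated correlation. Cyp2f2, a club cell enzyme, was at 6.69 ± 3.66 and 33.2 ± 29.4 CPM with passages summed and at 3.35 ± 3.93 and 34 ± 22.2 CPM at P8 (adjusted p = 0.713 and 0.488). AT1 genes took opposite directions by passage, with 0 called in each test (0 adjusted over the list alone). At P2 their median was -0.281 over 19 genes (list adjusted p = 0.0343, and adjusted p = 0.737 with an estimated correlation). With passages summed it was 0.282 over 21 genes (0.01, and adjusted p = 0.905 with an estimated correlation), and at P8 the list test was upward too over 18 genes (0.000223, and adjusted p = 0.76 with an estimated correlation). Of 19 unfolded protein response genes 0 passed (0 adjusted over the list alone; median 0.198, list adjusted p = 5.94e-05, and adjusted p = 0.723 with an estimated correlation). The disulfide isomerase Pdia3 was at 915 ± 51.4 and 1140 ± 76.5 CPM (0.32, adjusted p = 0.784). The chaperone Hyou1 was at 87.9 and 137 CPM (0.64, adjusted p = 0.783). Cholesterol synthesis had a median of -0.185 over 24 genes with 0 called (0 adjusted over the list alone; 0.000252, and adjusted p = 0.905 with an estimated correlation). The synthesis enzyme Cyp51 was at 474 and 350 CPM (-0.44, adjusted p = 0.896) and its regulator Srebf2 at 517 and 437 CPM (-0.24, adjusted p = 1). The gut genes Tff3, a mucosal trefoil peptide, and Cdh17, a gut cadherin, were at 25.5 ± 11.6 and 148 ± 94.1 CPM in young and 3.5 ± 2.74 and 27.4 ± 22.1 CPM in aged lines. Neither passed (log2 -2.86 and -2.44, adjusted p = 0.508 and 0.713). Their list of gut-like genes was not called (list adjusted p = 0.471). Its median over 26 genes was 0.209, higher in aged lines, with 0 higher and 1 lower adjusted over the list alone. Cell cycle genes at P8 had a median of -0.244 over 40 genes (list adjusted p = 4.69e-05, and adjusted p = 0.804 with an estimated correlation). NRF2 targets at P2 had a median of -0.175 over 24 genes (0.00167, and adjusted p = 0.737 with an estimated correlation). Replication-dependent histone genes had a median of 0.371 over 12 genes with passages summed (0.00439, and adjusted p = 0.723 with an estimated correlation). In these 3 lists 0 genes passed, also adjusted over the list alone. Of 33 iron genes 0 passed over all genes (1 higher and 1 lower adjusted over the list alone; list adjusted p = 0.498).

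Of 18398 genes tested with passages summed, Dmtn was the 1 that passed in edgeR, and 108 passed in DESeq2. At an unadjusted p under 0.05 there were 940, against 920 expected by chance. At P8 0 of 12024 passed in edgeR (855 at an unadjusted p under 0.05 against 601 expected by chance; 89 in DESeq2). For the difference between ages in the P2 to P8 change 0 of 12799 passed (632 against 640; 20 in DESeq2). Between the 2 young and 2 aged P0 lines 0 of 12106 passed (500 against 605; 18 in DESeq2). The preset list test called differences there as well, with medians of -0.77 over 40 cell cycle genes (list adjusted p = 1.77e-21), 0.728 over 31 integrated stress response genes (1.16e-19), 0.781 over 14 class I genes (1.4e-10) and -0.441 over 17 fibroblast markers (4.5e-05). Each has 0 genes called and adjusted p = 0.719 with an estimated correlation; adjusted over the list alone 1 class I gene was higher and 0 genes of the others passed. With sex of the line as a covariate, and without 8 of the 10 lines in turn, 0 genes passed with passages summed. Without AF1338 or without GH1493 2 did. At P2, 1 of 11959 passed (301 at an unadjusted p under 0.05 against 598 expected by chance), and leaving out any 1 line gave 1.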

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

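Tests of the AF1338 AT2 sample, of the library sets on the called genes and on the AT2 list, and of Dmtn against passaging, transformation and sex were chosen after the result was seen; the splits, the depth test, the hypoxia step and the segment test were set before.

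Other splits of the samples were run for each count. Chance can be excluded for the passage count, where the real exchange called 2712 genes and 1 of 100 exchanges, the real one, gave as many (highest other 212). For age at P2 (1 gene) 3 of 100 splits gave as many (highest other 1), and for age with passages summed (1 gene) 4 of 100 did. Both shares are under 0.05, the limit set before. Chance is still not excluded for a count of 1 gene, since splits other than the real one gave as many. With passages summed another split called 101 genes: AF1181, AF1338, GH1394, GH1397 and GH1493 against the rest. A split that calls so many points to a structure of the samples, and what its lines share was not tested. For age at P8 (highest other 2) and the interaction (highest other 0) the real count is 0, so 100 of 100 splits give as many by construction and the splits say nothing about chance. For P0 against P2 the 8 exchanges within lines are too few for a share under 0.05 (4894 genes; 1 exchange gave as many; highest other 0). With no replicate block 5474 genes passed and 1 of 35 splits gave as many (highest other 0), but only 8 of the 35 part all 4 pairs, so these too are too few.

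The AF1338 sample labelled AT2 carries tumor organoid genes. The 55 genes absent from the GH1493 AT2 library and at 50 CPM or more in AF1338 P1 lay at a median of 0.909 of their P1 level in it, against 0.196 in the AF1338 alveolar organoids. Across 10949 genes the sample had a correlation of 0.956 with AF1338 P1 and with AF1338 P2, and of 0.735 with the GH1493 AT2 sample. The likeness to tumor organoids is thus not limited to the 55 genes. Tumor organoid cells or RNA of the same line in that sample may account for this. A wrong label stays open, since these values cannot tell it from such a mixture. An exchange with another library of the 2 lines is argued against: 0 of the other 18 have the high Sftpc and absent Hnf4a of an AT2 sample. No biological explanation was tested.

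Genes called between P2 and P8 may follow the library set in place of passage. In the 2 lines whose share of reads outside genes stayed low, 52.2% of 3985 genes called in the 8 others kept their direction, against 51.7% of all genes tested, while between P3 and P6 of the 8 lines, inside one set, 81.4% of 3936 did (69.1% of all genes tested); the pair AF1338 and GH1493 was the lowest of 45 held-out pairs (54.6%; median 93.4%), so the set and a difference of these lines cannot be told apart. A first version of this check shared libraries with the calls and was replaced. The mean of the hypoxia list rose by a median over lines of 0.618 from P6 to P7 in the 8 lines, of 1.461 in all, and its cause stays open. Argued against is the set as the cause of the AT2 loss. The mean of the AT2 list had a median log2 change over lines of -3.775 in the 2 lines and -2.325 in the 8. Depth is argued against too, since 2602 genes passed with every library thinned to 5.18 M counts.

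Dmtn in the aged lines has age itself and the colony of the mice as open explanations, since all young lines carry AF codes and all aged lines GH or KW codes. Passaging is argued against, since at P0 the aged lines were already higher by log2 3.63 with no overlap, and sex by a difference of 3.66 among the male lines. Transformation stays open, since P0 may follow Cre and the alveolar organoids, with a difference of 2.49, come from 1 line of each age. A chromosome segment that separates the groups might account for it. The 76 genes within 5 Mb lie at percentile 88.3 of windows around other genes, and 11 of them had an unadjusted p under 0.05 for age. Such a segment and age cannot be told apart by these values.

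Single lines stood far from the others of their group in 9 of the 124 groups tested, where chance gives about 1 in 20 (6.2). In log2 CPM with passages summed these were AF1338 among young lines for Dmtn (0.321; others 1.74 to 1.87) and Nupr1 (9.75; 8.7 to 8.81), AF1183 for Hyou1 (7.06; 6.23 to 6.31), GH1394 among aged lines for Slc40a1 (6.23; 4.02 to 4.65), GH1397 for Sftpd (6.28; 8.46 to 8.95) and GH1493 for Ftl1 (12.8; 12.3 to 12.4). In log2 change they were AF1337 for Cdkn2a from P2 to P8 (2.46; -0.0451 to 1.15), and from P0 to P2 AF1165 for Psmb8 (-4.1; -5.16 to -4.99) and AF1337 for Col3a1 (-7; -5.44 to -5.4). The P2 to P8 change differed between ages, by the list test of the interaction, for AT2 identity (adjusted p = 3.04e-09), AT1 (1.74e-08), NRF2 target (4.17e-05) and iron-sulfur and heme genes (0.0447), all higher in aged; each has adjusted p = 0.313 with an estimated correlation. Xist, the RNA of the inactive X chromosome, had 8.88 CPM in the P0 library of the male line AF1165 and 72.8 CPM in the alveolar organoids of the male line GH1493, against 0 to 1.33 CPM in the 37 other libraries of male lines.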

How the results depend on the processing

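Alternatives with the share of reads outside genes or the library set as a covariate, P6 against P2, AF1338 and GH1493 alone, age without both of these lines, and leaving out AF1337, KW1401, a line with an AT2 sample or that sample in the paired comparisons were chosen after seeing the data; the rest were set before. The cause was not tested unless the alternative itself shows it by using fewer lines, samples or genes. A model with a sequencing batch was not run, since the deposited table gives none. Over all alternatives, 3570 list results and 10480 results for named genes kept their side of the threshold, and their direction where they passed. Another 310 and 537 no longer passed, 237 and 132 newly passed, and 1 and 26 turned sign. A turn of sign was counted for genes that passed in either fit and for lists that passed in both. Other changes of direction were not counted. With DESeq2 size factors all counts stayed within 1.5 times their value. The alternatives for lists include fry, a limma test that does not compare a list with the other genes. For AT2 identity its directional adjusted p was 0.00516 from P0 to P2 and 0.00244 from P2 to P8. For age the same list had 0.999 with passages summed and 0.258 at P8 in fry.

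For age with passages summed (1 gene), DESeq2 called 108 and limma-voom with the line as a random effect 149. Limma-trend on means per line called 0 (smallest adjusted p 0.0555), and a sex covariate 0. Leaving out 1 line gave 0 to 2, and leaving out both lines with AT2 libraries 3. At P2 (1 gene) DESeq2 called 5 and the sex covariate 2. At P8 (0 genes) DESeq2 called 89, no filter on low counts 1, leaving out 1 line 0 to 8 (8 without AF1338, 1 without GH1493), leaving out both 11, and the covariate for reads outside genes 1. DESeq2 called 20 for the interaction and 18 at P0, in place of 0. Planted genes gave DESeq2 more false calls than edgeR in each of these designs that was tested.

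From P2 to P8 (2712 genes) no filter gave 5510, slopes over all passages 5559, AF1338 and GH1493 alone 170, and the covariate 5. No replicate block gave 2004. From P0 to P2 (4894) the covariate gave 2234 and leaving out 1 line 3367 to 4321. P8 in place of P2 gave 5029, 3307 shared and 24 of them opposite. From AT2 to alveolar organoid (1868) no replicate block gave 1196, only the 4 libraries compared 0 in edgeR (1250 at an unadjusted p under 0.05), and leaving out AF1338 or GH1493 3266 or 2528. From alveolar organoid to P1 (2050) no replicate block gave 1227, only the 4 libraries 5491, leaving out the AF1338 AT2 sample 4172, and leaving out 1 line 1606 to 2140.

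Log2 fold changes that turned sign were, from P2 to P8, with P7 against P3 Hist1h1e at -0.022. With P6 against P2 they were Csf2 at -0.414, Hist1h1e -0.104, Hmga2 -0.299, Hsp90b1 -0.121, Myc -0.038 and Vwf 0.404. In AF1338 and GH1493 alone they were Egln1 at -0.046, Fth1 -0.039, Herpud1 -0.152, Hist1h1c -0.452, Igf2bp2 -0.066, Lamc2 0.019, Lcn2 -6.478 (adjusted p = 0.0158), Lgr4 -0.182, Mcm2 0.278, Pcbp1 -0.014, Sdhc -0.033 and Vwf 0.545. From P0, all libraries without a block gave Ly6d at 0.949, and P8 in place of P2 gave Ero1l at 1.782 (adjusted p = 0.00463), Herpud1 at 0.274 and the hypoxia list up (adjusted p = 0.00181). From AT2 to alveolar organoid without AF1338, Cdkn2a was at 7.389, Ctse 8.546, Hmga2 8.384 and Mki67 4.771. In GH1493 the AT2 sample has 0 counts of Cdkn2a, Ctse and Hmga2, so those values are no bounds; against a floor of 3 counts its alveolar organoids were at least 4.16, 9.31 and 8.32-fold higher. A lone sample is assumed to vary like the other groups. Without GH1493 Cdkn2a was at -2.833, Ctse -6.476, Hmga2 -1.49 and Mki67 -1.547. With every library thinned to 5.18 M counts 2602 genes passed from P2 to P8, 2487 of them among the 2712.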

Other observations

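The values below were chosen after the result was seen. Alveolar type 1 (AT1) genes, of the flat gas exchange cell, fell with the AT2 genes from P0 to P2: of 21 measured 16 fell and 1 rose (17 and 1 adjusted over the list alone; list adjusted p = 3.76e-08, and adjusted p = 0.179 with an estimated correlation). Ager, the AT1 receptor for glycation products, went from 4390 to 525 CPM (log2 fold change -3.17, SE 0.286; n = 4 lines). Interferon response genes had 14 of 23 lower and 0 higher (15 and 1 adjusted over the list alone; 0.000327, and adjusted p = 0.504 with an estimated correlation). Other rising genes include Onecut2 of the gut-like list, a transcription factor of liver and neurons (0.337 to 40.5 CPM, log2 7.05, SE 0.602). Of 25 NF-kB list genes 12 rose and 7 fell. The risen ones include the interleukin 1 receptor antagonist Il1rn (0.773 to 94.2 CPM, log2 6.92, SE 0.496) and the chemokine Cxcl5 (9.28 to 259 CPM, log2 4.91, SE 0.256). From P2 to P8 AT1 genes had 10 of 19 lower and 2 higher (14 and 3 adjusted over the list alone; 5.38e-05, and adjusted p = 0.351 with an estimated correlation), and the integrin subunit Itgb6 fell from 307 ± 101 to 124 ± 60.8 CPM (-1.46, SE 0.18).

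Trp53 was at 82.7 CPM in the AF1338 and 73.5 CPM in the GH1493 alveolar organoids, 22.3 ± 5.18 CPM in the 4 P0 libraries, 10.8 ± 3.75 CPM at P2 and 7.88 ± 1.71 CPM at P8 (n = 10 lines each). Hnf4a was listed at 0 in both alveolar organoid libraries, at 6.21 ± 3.47 CPM at P0, 31.3 and 41.6 CPM in the P1 libraries and 89.9 ± 53.3 CPM at P2. The GH1493 AT2 sample also held Igha, an immunoglobulin heavy chain of plasma cells, at 2180 CPM, the club cell gene Scgb1a1 at 2140 CPM and the endothelial gene Vwf at 78.1 CPM, against 6.4, 55.1 and 1.56 CPM in the AF1338 AT2 sample.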
